A study of Nannospalax ehrenbergi and Mus musculus with 90 samples.

How the data were processed

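The series holds 90 samples of 3 kinds from the blind mole rat Nannospalax ehrenbergi and the laboratory mouse. RNA was sequenced from 6 fibroblast libraries of the mole rat, 3 labelled young and 3 labelled old. Methylated DNA of fibroblasts was enriched with an antibody and sequenced (MeDIP) in 4 libraries, 2 young and 2 old. RNA was also sequenced from 8 tissues of 5 mole rats and 5 mice, which makes 80 libraries. Per the labels, fibroblasts were grown at 37 °C in 3% O2 and 5% CO2 with 15% serum. The labels do not state what old and young mean for the fibroblasts, nor whether the libraries of a group came from separate cultures. Groups and animal numbers were taken from the sample labels.

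The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.2b, Salmon 1.4.0, edgeR without a version, R 3.3.2 and the mouse build mm10, with no role or order. The mole rat build and the annotation releases were not given in the sources used here. For the fibroblasts, the authors deposited 1 table of reads scaled to the sum of the library (RPM) for 24636 Ensembl mole rat genes, 17313 of them with a human gene name, per the file headers. Each RPM column summed to 1 M, and 100.0% of its values were whole multiples of 1 read within 0.05 reads, so whole reads were recovered. For the tissues, the authors deposited 1 Salmon table per library with the effective length, the TPM and the estimated counts (expected counts) of each transcript, per the file headers. TPM was relative to all transcripts of that species' table. The mole rat tables list 54559 RefSeq transcripts with gene symbols, and the mouse tables list 66395 GENCODE transcripts without symbols. For MeDIP, the authors deposited 1 table of 100 bp windows kept at an adjusted p-value under 0.1. Per the file headers it holds read counts, RPKM and a relative methylation score for each of the 4 libraries, the number of CpG sites per window (the coupling factor), and the log2 fold change and p-value of the authors' own edgeR comparison. The formula of the methylation score was not given in the sources used here, and the score was not used.

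The test for the fibroblasts was written for raw counts or, if the table held normalized values, for those values. Since the table holds RPM, limma-trend (limma, version 3.58.1, R 4.3.3) was run on log2(RPM + 0.5) for genes at 1 RPM or more in at least 3 of the 6 libraries. Fold changes are on the log2(RPM + 0.5) scale, which understates the change of low genes. edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads as added alternatives. Mouse transcripts were given gene names from a reference table, which named 62738 of them and left 3657 without a name. Transcripts were summed to gene symbols, and the 14857 symbols found in both species (case ignored) were compared. Another 9906 mole rat symbols begin with LOC and were matched to no mouse gene. TPM was then rescaled to a total of 1 M over the shared symbols in each library, and printed TPM values are on that scale. The expected counts were rounded to whole numbers and tested in each tissue with edgeR's quasi-likelihood test, with TMM scaling, the default expression filter, and the effective length per gene and library as an offset, since the transcript models differ between the species. A species by tissue interaction was tested in 1 edgeR model over the 80 libraries with animal and tissue as terms. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, with no fold threshold. Differences are old minus young, and mole rat minus mouse.

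Gene lists fixed before the data were examined were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, where at least 5 members were measured. Of 36 lists, 20 had enough members in the fibroblasts. The other 16, among them the epithelial, endothelial, T cell, neutrophil and mitochondrially encoded genes, had at most 4 tested members. In the tissues 272 combinations of list and tissue were tested. Named genes were set by rule. For the fibroblasts these are the 10 called genes with the largest change in each direction that have a mean of 1 RPM or more, groups that do not overlap and a gene name. For the tissues these are the 8 genes in each direction called in all 8 tissues, with a mean of 5 TPM or more in at least 1 species in every tissue and the largest minimum change, and per tissue the 3 in each direction with a mean of 5 TPM or more in both species. Up to 4 members of each list and 12 key genes were added. Some of the named genes and 1 of the lists are not described. Of the key genes, Apobec3 had no row in the fibroblast table, and Sting1 and Apobec3, among others, had no symbol shared by both species in the tissues. Gene names shared by several identifiers stay uncertain: 1290 tested fibroblast genes share a human name with another gene.

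Recovered fibroblast libraries held 27.7 to 38 M (mega) reads. Tissue libraries held 40.2 to 84.2 M estimated reads in mole rats and 69.6 to 136 M in mice, of which 33.9 to 65.2 and 36.0 to 73.1 M fell in shared symbols. A gene with no read was treated as lying under 3 counts per library, a limit that covers counting error only. The fibroblast fits with limma, edgeR and DESeq2 and the liver fits with edgeR and DESeq2 were tested on simulated data drawn from the real means and library sizes, and the other fits were not. In the fibroblasts limma called 99 of 100 genes changed by 1 on the log2 scale and 100 of 100 changed by 2, with 9 false calls among 12364 tested genes. In the liver edgeR with the length offset called 36 of 100 genes changed by 1 and 100 of 100 changed by 2, with 3 false calls among 12352. Without the offset it made 1894 false calls. The deposited lengths were built into the simulated means, so this does not test whether the offset suits the real data. The simulated spread between replicates was a fixed value for all genes, and few genes were changed, as many up as down. In the real fibroblasts and liver most tested genes were called, so these rates need not hold there. In the simulated fibroblasts camera called the shifted list and 0 of 18 lists that share no gene with it. Genes were drawn independently of each other, so the simulation could not test camera on correlated genes. In the real fibroblast libraries the estimated correlation was 0.405 for ribosomal proteins.

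The alternatives were other scalings, filters, pseudocounts and tools, no length offset, an absolute log2 fold change over 1, the replicate number as a block, and leaving out each library in turn. The tests on recovered reads, the TMM-scaled RPM and the fits on some of the mole rats were added after seeing the data. Other splits of the samples were counted over all 10 splits of the fibroblast libraries, 40 of the 126 splits of the animals for the tissues and 21 for the interaction, the last on 4000 genes drawn at random. The numbers of tissue splits and of interaction genes were reduced to shorten the run time, after longer runs had been seen. Transposon families were not tested, because the tables read here have no transposon features. Methylation was not linked to expression, because the window table names no genes and no mole rat genome was used here. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and plots.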

Results

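The blind mole rat Nannospalax ehrenbergi is a long-lived subterranean rodent in which tumours are rarely seen. Gene expression was measured by RNA sequencing in its cultured fibroblasts, in 3 libraries labelled young and 3 labelled old, and in 8 tissues of 5 mole rats and 5 mice (liver, kidney, lung, spleen, skeletal muscle, skin, intestine and white adipose tissue). DNA methylation of fibroblasts was measured by MeDIP, which sequences DNA fragments bound by an antibody to methylated cytosine, in 2 old and 2 young libraries. The young fibroblast RNA libraries held 27.7, 38 and 33.6 M (mega) recovered reads and the old ones 31.6, 32.5 and 30.2 M. Tissue libraries held 40.2 to 84.2 M estimated reads in mole rats and 69.6 to 136 M in mice. Pearson's r of log2 RPM across genes was 0.993 to 0.998 between fibroblast libraries of 1 group and 0.908 to 0.913 between groups. In the tissues the markers of each organ were highest in the libraries of that organ in all 16 groups of 5 libraries.

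The first comparison asked which genes differ between old and young mole rat fibroblasts. Genes induced by interferon and genes of cell division were higher in the old libraries, and macrophage markers and contractile genes were lower. MX1 (ENSNGAG00000017263), an antiviral GTPase induced by interferon, rose from 0.706 ± 0.0712 RPM in young to 747 ± 37.9 RPM in old fibroblasts (SD, n = 3 each), and the log2 fold change was 9.28 (SE 0.07, limma adjusted p = 1.4e-12). IFNB1 (ENSNGAG00000018797), which encodes interferon beta, had 0 reads in the 3 young libraries and 1.75 ± 0.166 RPM in the old ones (n = 3), at least 19-fold over the floor of 3 reads per library (limma adjusted p = 2.5e-07). MMP9 (ENSNGAG00000007661), a gelatinase secreted by leukocytes among other cells, fell from 132 ± 2.28 to 0.159 ± 0.109 RPM (n = 3 each), with a log2 fold change of -7.67 (SE 0.11, limma adjusted p = 5e-11). HAS2 (ENSNGAG00000013602), the synthase of long hyaluronan chains, rose from 95.7 ± 2.95 to 606 ± 27.9 RPM (log2 fold change 2.66, SE 0.05).

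Of 12450 genes tested, limma called 8542, of which 5047 were higher and 3495 lower in old fibroblasts. The change exceeded 1 on the log2 scale in 867 of the higher genes, and it was under -1 in 955 of the lower ones. The 3 old values lay apart from the 3 young values in 8949 of all tested genes (71.9%), and chance alone separates 10% of genes in this way. The p-values measure only the spread between these libraries, which may be technical, since the labels name no separate cultures. The split between higher and lower depended on the scaling: with TMM-scaled RPM 4066 genes were higher and 4351 lower, and edgeR on recovered reads with TMM gave 4206 and 4710, as TMM moved the median of all genes from 0.09 to -0.02, a shift of 0.11.

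The 10 genes with the largest rise were MX1, CXCL3, IL1A, OAS1, USP41, ISG15, CXCL6, OASL, SELP and ACOD1. OAS1 and OASL, of the family of 2'-5'-oligoadenylate synthetases, rose from 0.43 to 96.8 RPM and from 0.149 to 41.8 RPM. ISG15, a ubiquitin-like modifier induced by interferon, rose from 1.68 ± 0.247 to 181 ± 15.6 RPM (n = 3 each). The neutrophil-attracting chemokines CXCL3 and CXCL6 rose from 5.25 to 851 RPM and from 22.2 to 1821 RPM. IL1A, the cytokine interleukin 1 alpha, rose from 2.01 to 293 RPM, and SELP, the adhesion molecule P-selectin, from 4.34 to 278 RPM. ACOD1, the enzyme that makes itaconate, averaged 0.0485 RPM in young libraries and 19.3 RPM in old ones, and USP41 rose from 0.952 to 135 RPM. OAS1, OASL, CXCL3, CXCL6 and USP41 belong to families of similar copies, so their reads remain uncertain between the copies. The 10 genes with the largest fall were MMP9, SERPINB10, PF4V1, MSR1, C1QA, LYZ, ITGAM, ITGB2, CDH3 and C1QC. MSR1, a scavenger receptor of macrophages, had 68.3 ± 0.715 RPM in young and 0.011 ± 0.0191 RPM in old libraries (n = 3 each). C1QA and C1QC, subunits of complement C1q, had 73.0 and 33.8 RPM in young libraries. In old ones C1QA had 0.0519 RPM and C1QC had 0 reads, at least 354-fold lower than in young against the floor of the old libraries. ITGAM and ITGB2, the chains of a leukocyte integrin, fell from 49.4 to 0.0103 RPM and from 50.7 to 0.0858 RPM. SERPINB10, a protease inhibitor, fell from 136 to 0.242 RPM, and CDH3, the adhesion molecule P-cadherin, from 72.8 to 0.509 RPM. LYZ, lysozyme, and PF4V1, a platelet chemokine, are members of families with similar copies and fell from 54.1 to 0.0211 RPM and from 96.3 to 0.0522 RPM.

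**Figure D1:**
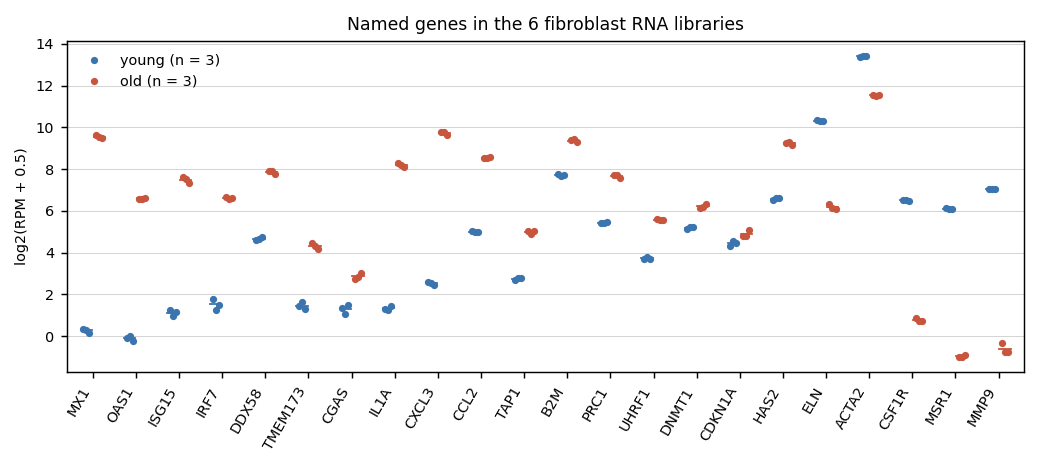
Levels of named genes as log2(RPM + 0.5) in each of the 3 young and 3 old fibroblast libraries, with 1 point per library and a line at the mean. MX1 lies near 0.706 RPM in young and near 747 RPM in old libraries, and MMP9 moves from 132 to 0.159 RPM.

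Among the gene lists, 8 were called higher and 4 lower by camera, of 20 tested. The other 9 splits of the libraries, with 0 genes called each, still gave 7 to 10 lists. A camera call by itself therefore does not set old against young apart from other splits, and the counts of members are the measured result. Of 37 measured interferon-stimulated genes, 34 rose and 1 fell, with a median log2 fold change of 2.40 (camera adjusted p = 2.97e-13; adjusted p = 0.021 with an estimated correlation). Of 24 genes that sense foreign or misplaced nucleic acids, 19 rose and 3 fell (camera adjusted p = 0.00184; adjusted p = 0.139 with an estimated correlation). In this list DDX58, which encodes the RNA sensor RIG-I, rose from 24.8 to 232 RPM, IFI16, a DNA sensor, had a log2 fold change of 3.51, and RNASEH2B, a subunit of the enzyme that removes RNA from DNA hybrids, fell with a log2 fold change of -1.72. CGAS, which senses DNA in the cytosol, rose from 1.96 ± 0.388 to 6.79 ± 0.811 RPM, and TMEM173, which encodes its partner STING, from 2.25 ± 0.337 to 19.5 ± 1.76 RPM (n = 3 each). IRF7, a transcription factor of the interferon response, rose from 2.39 to 97.3 RPM. All 13 measured genes of antigen presentation by MHC class I rose (camera adjusted p = 8.64e-05; adjusted p = 0.0434 with an estimated correlation), among them B2M, the light chain of the complex, from 211 to 657 RPM, and NLRC5, its transactivator, with a log2 fold change of 2.90. Of 10 interferon ligands, receptors and their kinases 6 rose and 2 fell, and the list was not called (camera adjusted p = 0.281). IL10RB and JAK2 rose, with log2 fold changes of 1.04 and 0.65, and SOCS3, an inhibitor of cytokine signalling, fell (-1.22).

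All 46 measured genes of the cell cycle and DNA replication rose, with a median log2 fold change of 1.94 (camera adjusted p = 1.04e-17; adjusted p = 0.0434 with an estimated correlation). TK1, a thymidine kinase of S phase, rose from 9.73 to 66.2 RPM, and the mitotic genes KIF11, PRC1 and CDC20 had log2 fold changes of 2.30, 2.24 and 2.24. Of 30 inflammatory and secretory factors 21 rose and 8 fell (median 2.18, camera adjusted p = 0.00184; adjusted p = 0.085 with an estimated correlation). CCL2, a chemokine that attracts monocytes, rose from 31.6 ± 0.918 to 372 ± 8.45 RPM (n = 3 each). Of 33 genes that silence transposons 20 rose and 3 fell (camera adjusted p = 0.00712; adjusted p = 0.085 with an estimated correlation), among them MOV10, an RNA helicase that restrains retroelements, with a log2 fold change of 1.31, and TEX15, known from the germline, with 0.88. Of 29 antioxidant genes 18 rose and 3 fell over all genes, or 19 and 3 adjusted over the list alone (camera adjusted p = 0.0082; adjusted p = 0.489 with an estimated correlation), and SOD2, the mitochondrial superoxide dismutase, rose from 1098 to 3948 RPM. Of 22 ribosomal protein genes 13 rose, with a median of 0.24, and camera called the list (adjusted p = 0.0256; adjusted p = 0.545 with an estimated correlation), but not on TMM-scaled RPM (adjusted p = 0.0531).

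The lists called lower in old fibroblasts were macrophage markers, contractile genes, extracellular matrix genes and cholesterol synthesis genes. All 12 measured macrophage markers fell, with a median log2 fold change of -4.78 (camera adjusted p = 9.87e-11; adjusted p = 0.021 with an estimated correlation), and CSF1R, the receptor of a macrophage growth factor, went from 90.3 ± 0.763 to 1.19 ± 0.0948 RPM (n = 3 each). Of 15 myofibroblast and contractile genes 14 fell and 0 rose, or 15 fell adjusted over the list alone (median -1.09, camera adjusted p = 1.37e-08; adjusted p = 0.021 with an estimated correlation). ACTA2, smooth muscle actin, fell from 10890 to 2983 RPM, and MYH11, smooth muscle myosin, from 72.2 to 2.33 RPM. Of 30 extracellular matrix genes 20 fell and 7 rose (camera adjusted p = 5.03e-04; adjusted p = 0.191 with an estimated correlation). ELN, elastin, fell from 1285 ± 26.5 to 72.4 ± 6.59 RPM (n = 3 each), while FBLN5 and COL5A1 had log2 fold changes of -2.35 and -1.30. Of 21 cholesterol synthesis genes 14 fell and 3 rose (camera adjusted p = 5.11e-04; adjusted p = 0.0768 with an estimated correlation), and INSIG1, which holds back sterol synthesis, fell from 42.5 to 14.9 RPM.

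**Figure D2:**
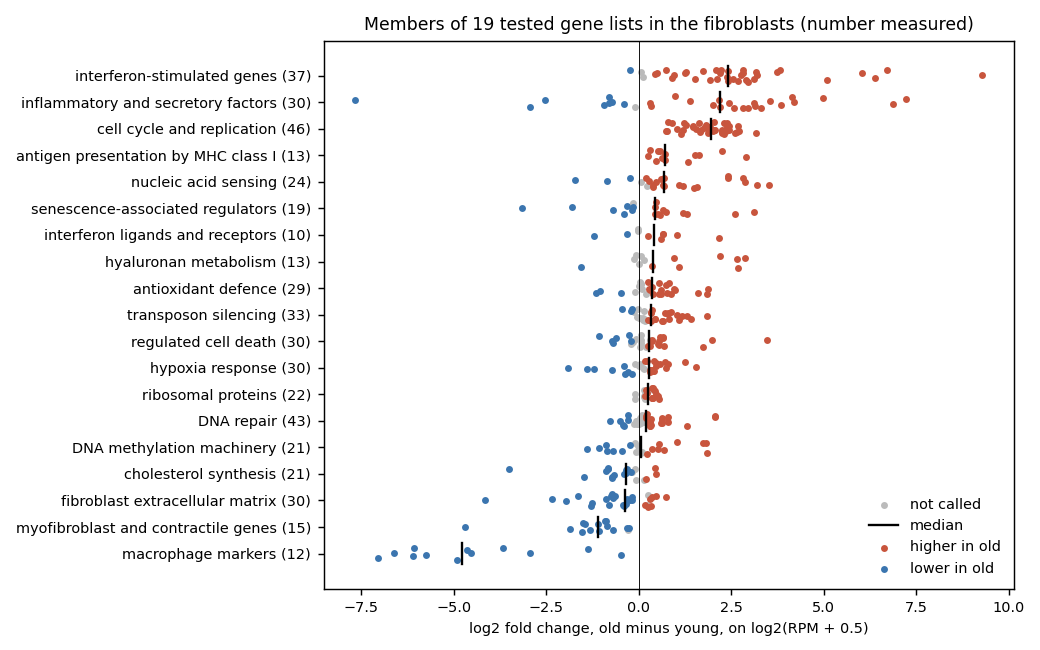
Log2 fold changes, old minus young, of the measured members of the fixed gene lists in fibroblasts, with 1 point per gene and the median of each list marked. The median is 2.40 for interferon-stimulated genes, 1.94 for cell cycle genes and -4.78 for macrophage markers.

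Other lists held changes in both directions and were not called by camera, which compares a list with all other genes. Fry, which tests a list by itself, called all 20 lists tested. Of 21 genes of DNA methylation 9 rose and 7 fell (median 0.07, camera adjusted p = 0.839). DNMT1 (ENSNGAG00000010277), which copies methylation to new DNA strands, rose from 36.0 ± 1.58 to 74.4 ± 5.09 RPM, and UHRF1 (ENSNGAG00000022853), its partner at replicated DNA, from 12.8 ± 0.421 to 47.3 ± 1.01 RPM (n = 3 each), with log2 fold changes of 1.04 and 1.85. HELLS and CDCA7, which remodel chromatin for methylation, rose with log2 fold changes of 1.82 and 1.72. CDKN1A, the cell cycle inhibitor p21, rose from 21.3 ± 1.82 to 29.0 ± 3.51 RPM (n = 3 each, limma adjusted p = 0.0027). FAS, a death receptor, rose with a log2 fold change of 1.98, and DDIT4 and BTG2 fell, with -1.41 and -1.48. Of 19 senescence regulators 11 rose and 7 fell (camera adjusted p = 0.656). CDKN2B, the inhibitor p15, rose from 2.76 to 27.1 RPM, and CDKN1C, the inhibitor p57, fell from 23 to 2.10 RPM. Of 30 cell death genes 14 rose and 6 fell (camera adjusted p = 0.281), with NLRP3, of the inflammasome, at a log2 fold change of 3.47. Of 30 genes of the hypoxia response 17 rose and 8 fell (camera adjusted p = 0.386), and EPAS1, a hypoxia-inducible factor, fell from 213 to 56.9 RPM. Of 13 hyaluronan genes 7 rose and 1 fell (camera adjusted p = 0.0619). CEMIP and HMMR rose with log2 fold changes of 2.20 and 2.68, VCAN fell with -1.55, and HPSE, heparanase, rose from 1.36 to 3.50 RPM. Of 43 DNA repair genes 22 rose and 6 fell, or 20 and 6 adjusted over the list alone (camera adjusted p = 0.148), with BRCA1 and CHEK1 at 2.05 and 2.06. In the other 17 lists tested the counts adjusted over the list alone were the same as over all genes.

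The second comparison used the authors' deposited table of MeDIP windows, which lists windows of 100 bp that differed between old and young fibroblasts at an adjusted p under 0.1. The authors' deposited table holds 573 windows, 440 with lower and 133 with higher methylation signal in old fibroblasts, on 37 scaffolds. Its p-values and adjusted p-values imply that the authors' edgeR comparison tested about 8.61 M windows. In the authors' deposited table a group of 405 windows (70.7%) lies on 1 scaffold between positions 73201 and 223700, all lower in old cells, with a median log2 fold change of -1.29 and a range from -2.03 to -0.92. Median RPKM per window there was 22.2 and 18.5 in the old libraries and 41.9 and 44.2 in the young ones in the authors' deposited table. A second scaffold holds 95 windows between positions 6536201 and 6664700, all higher in old cells in the authors' deposited table, with a median log2 fold change of 3.12 and median reads per window of 19 and 20 in the old libraries and 1 and 2 in the young ones. In the authors' deposited table the top 4 scaffolds hold 525 windows (91.6%), and the other 48 windows (35 lower, 13 higher) are spread over 33 scaffolds. The windows hold 1 to 8 CpG sites with a median of 1. The series holds no fibroblast DNA library without the antibody, so methylation cannot be separated from the amount of DNA at a position. The scaffold build was not given in the sources used here and the table names no genes, so no window was assigned to a gene, and windows that did not pass the authors' threshold were not analysed here. With 2 libraries per group no test of the windows was run anew, and 332 windows in the authors' deposited table (311 lower, 21 higher) have an adjusted p under 0.01.

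**Figure D3:**
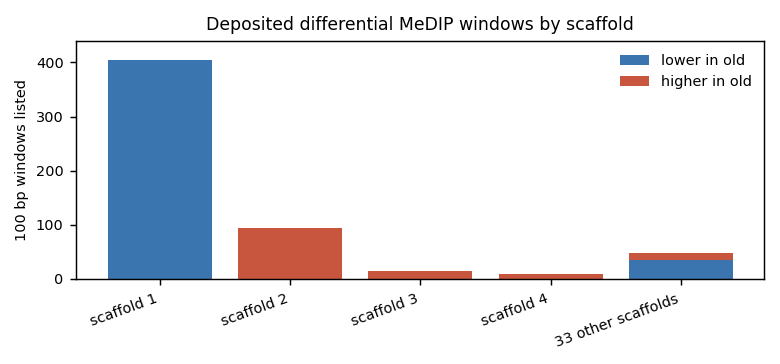
Number of 100 bp windows in the authors' deposited table per scaffold, for the 4 scaffolds with most windows and the other 33 together, split into lower and higher methylation signal in old fibroblasts. The scaffold with most windows holds 405, all lower, and the next holds 95, all higher.

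The third comparison asked how gene expression differs between mole rats and mice in each tissue. Of the measured interferon-stimulated genes, more were lower than higher in mole rats in each of the 8 tissues. The list holds 60 symbols, and mole rat reads of copies named LOC were not joined to them. Whether this lowered the mole rat values was not tested. Of the measured members, edgeR called 7 higher and 21 lower in liver, 5 and 27 in kidney, 7 and 26 in lung, 6 and 10 in spleen, 4 and 27 in muscle, 0 and 29 in skin, 2 and 21 in intestine, and 1 and 30 in white adipose tissue, of 40 or 41 measured. Adjusted over the list alone the lower members were 22 in liver, 29 in muscle, 30 in skin and 31 in white adipose tissue, where 2 were higher, and the other counts were the same. Zbp1, a sensor of left-handed nucleic acids, was lower in all 8 tissues, with log2 fold changes from -8.15 in liver to -3.45 in spleen, and so were Herc6 (-6.88 to -3.05), Samd9l (-4.40 to -1.29) and Helz2 (-2.85 to -0.54, with the call in skin lost without mouse 4). Camera called the list lower in kidney (adjusted p = 0.019), lung (0.037), muscle (0.0014), skin (2.6e-06), intestine (4.5e-04) and white adipose tissue (9.6e-05), and in no tissue with an estimated correlation (adjusted p = 0.99). In spleen the median of the list was 0.04 and the mean -0.18, but without mole rat 2 the list had 6 higher and 23 lower members and a median of -0.88.

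Irf7 was lower in mole rats in 6 tissues, with the largest differences in intestine (12.8 ± 4.13 against 192 ± 98.2 TPM, n = 5 each) and skin (5.87 ± 1.47 against 51.3 ± 29.9 TPM, n = 5 each). Isg15 was higher in mole rat liver (124 ± 112 against 22.7 ± 6.47 TPM, log2 fold change 2.36, or 1.76 without mole rat 1) and lung (94.9 ± 35.7 against 31.1 ± 10.6 TPM) and lower in skin (12.5 ± 5.65 against 40.9 ± 12.6 TPM, n = 5 each). Cgas was lower in 6 tissues, with log2 fold changes from -2.04 in intestine to -0.61 in skin. Leaving out single animals ended the call of Cgas in kidney for 8 of the 10, in muscle and skin for 7 each, in liver for 6 and in lung for 4. Of 25 nucleic acid sensing genes 9 to 16 were lower and 2 to 8 higher per tissue, and camera called the list lower in skin (adjusted p = 0.039) and white adipose tissue (0.037; adjusted p = 0.99 with an estimated correlation in both). Tlr7, a sensor of single-stranded RNA, ranged from -7.26 in skin (-6.34 without mouse 5, -8.06 without mole rat 4) to -0.70 and was lower in all 8 tissues, as were Ticam1 (-4.19 to -1.97) and Rnaseh2c (-4.37 to -1.81). Adar, which edits double-stranded RNA, was lower in all 8 (-1.81 to -0.35), but without the length offset its log2 fold change was 0.05 in kidney and 0.13 in muscle and passed the test in neither. Without the offset its calls in liver and white adipose tissue were lost as well. The call of Adar in muscle was lost without any of 4 of the 10 animals. Of 15 MHC class I presentation genes 12 were lower in skin (camera adjusted p = 1.5e-04) and 11 in white adipose tissue (adjusted p = 0.015; 0.99 with an estimated correlation in both), or 13 in each adjusted over the list alone. B2m was lower in 7 tissues, from -4.12 in skin, but in spleen (-1.44, or -2.08 without mole rat 2) its log2 fold change without the length offset was 0.56 and did not pass the test. In skin T cell markers averaged 1.42 to 1.84 on the log2(TPM + 0.5) scale in mole rats and 2.18 to 3.17 in mice, with 6 of 11 lower and 1 higher (camera adjusted p = 0.22), and macrophage markers averaged 4.24 to 5.19 and 3.76 to 7.41. Macrophage markers averaged 3.45 to 4.62 in mole rats and 4.97 to 5.58 in mice in liver, 2.78 to 3.61 and 3.39 to 4.01 in kidney, 2.81 to 3.27 and 3.14 to 4.01 in muscle, and 3.68 to 4.15 and 4.05 to 5.14 in intestine. T cell markers averaged -0.07 to 1.14 and 0.72 to 2.31 in kidney and -0.44 to 0.5 and 0.05 to 2.96 in muscle. In liver they averaged 0.62 to 1.21 and 0.71 to 1.54, and in intestine 3.03 to 3.95 and 2.52 to 4.21. In lung T cell markers averaged 3.02 to 5.06 and 3.1 to 4.34, and macrophage markers 5.45 to 5.88 and 5.63 to 6.03. In white adipose tissue T cell markers averaged 1.84 to 4.2 and 1.82 to 4.64, and macrophage markers 5.16 to 7.34 and 6.39 to 7.4. Fewer immune cells and lower expression in each cell cannot be separated in these tables. Tyk2, a kinase of the interferon receptor, was lower in all 8 tissues (-2.15 to -0.88).

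**Figure D4:**
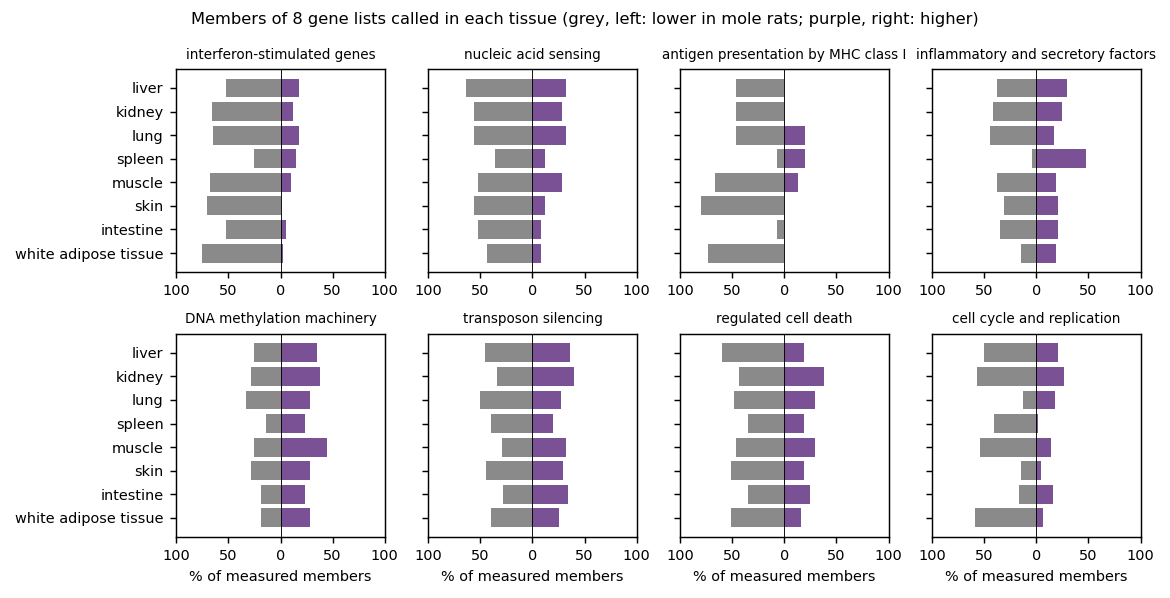
Percent of the measured members of 8 gene lists that were lower (grey, to the left) or higher (purple, to the right) in mole rats than in mice in each of the 8 tissues. Of the interferon-stimulated genes 10 were lower in spleen and 30 in white adipose tissue.

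Dnmt1 was lower in mole rats in 6 tissues, with 49.9 ± 16.0 against 113 ± 37.2 TPM in spleen (log2 fold change -1.29, edgeR adjusted p = 0.0023, n = 5 each), while in muscle (5.61 ± 0.309 against 5.40 ± 1.84 TPM, adjusted p = 0.65) and white adipose tissue (26.0 ± 2.78 against 27.2 ± 5.55 TPM, adjusted p = 0.068) it did not pass the test. Uhrf1 was lower in kidney (-2.43), muscle (-3.92, or -2.99 without mouse 5) and white adipose tissue (-1.59). Tet3, which oxidizes methylcytosine, was lower in all 8 tissues (-2.66 to -1.43). Of 20 or 21 measured genes of DNA methylation 5 to 9 were higher and 3 to 7 lower per tissue, and of 33 to 36 transposon silencing genes 7 to 14 were higher and 10 to 18 lower, and camera called neither list in any tissue. Ehmt1, Mphosph8 and Sirt6, which act in repressive chromatin, were higher in all 8 tissues, with smallest log2 fold changes of 0.64, 0.48 and 0.64 (Sirt6 in spleen, a call lost without any of 3 of the 10 animals), and Sirt7 was lower in all 8. Cdkn1a was higher in mole rat kidney (33.4 ± 17.4 against 8.22 ± 2.25 TPM), lung (182 ± 63.3 against 44.9 ± 10.2 TPM) and intestine (192 ± 28 against 88.3 ± 16.5 TPM, n = 5 each). Mdm2 was higher in 7 tissues. Has2 was lower in kidney (-1.15, lost without any of 7 of the 10 animals), spleen (-1.74) and white adipose tissue (-1.19) and was not called higher in any of the 7 tissues where it was tested. Hpse was lower in liver (-1.82) and muscle (-1.67) and higher in lung (1.35) and spleen (0.80, or 0.69 and not called without mouse 4). Fadd, an adaptor of death receptors, was higher in all 8 tissues (1.19 to 2.26, with the calls in spleen and muscle lost without the length offset), and Casp2 was lower in all 8 (-2.21 to -0.99). Timp1, an inhibitor of metalloproteases, was higher in all 8 tissues (2.89 to 6.11, or 2.14 in spleen and 2.28 in white adipose tissue without mole rat 2). DESeq2 did not call Timp1 in spleen. Without 1 mouse Timp1 was 4.09 in intestine (mouse 1), 3.57 in liver (mouse 2) and 4.54 in kidney (mouse 3), in place of 2.97, 2.96 and 3.63. Icam1 was lower in 7 tissues, with the call in spleen lost without any of 8 of the 10 animals.

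**Figure D5:**
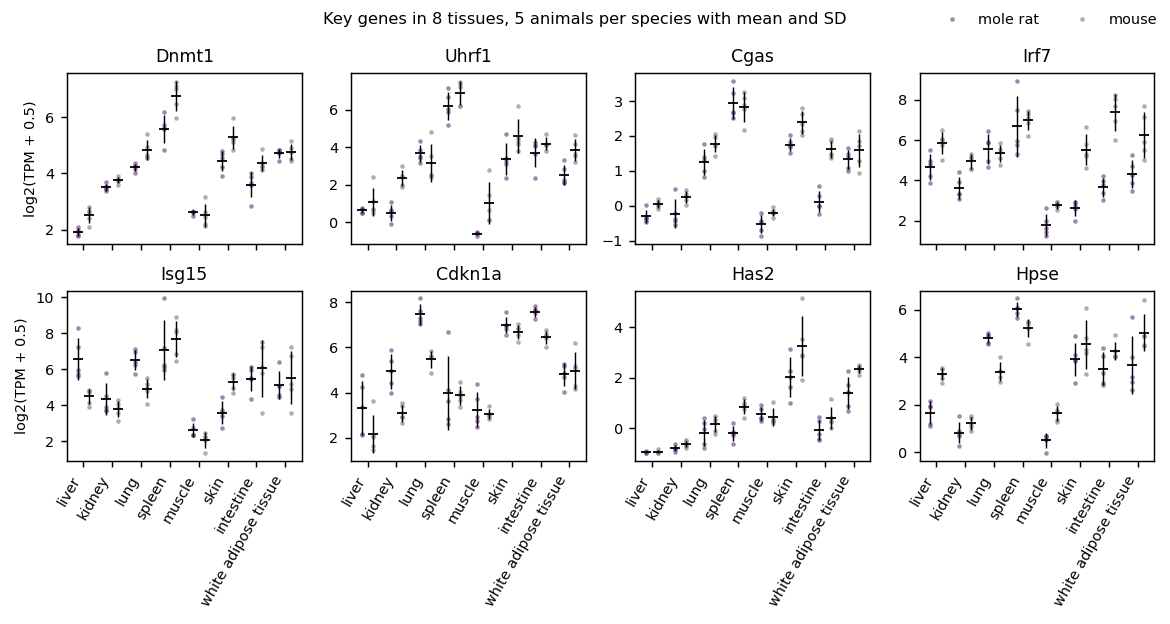
Levels of key genes as log2(TPM + 0.5) in each animal, with 5 mole rats and 5 mice per tissue and bars for the mean and SD. Dnmt1 in spleen averages 49.9 TPM in mole rats and 113 TPM in mice.

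Most genes differed between the species. EdgeR called 8511 of 12029 genes in liver (4269 higher in mole rats), 10008 of 13199 in kidney (5096 higher), 9921 of 13436 in lung (5085), 7213 of 12847 in spleen (3835), 8983 of 12303 in muscle (4489), 7518 of 13432 in skin (3780), 7099 of 13110 in intestine (3531) and 7927 of 13274 in white adipose tissue (4229). The share of calls that were higher was 49.7 to 53.3% over the tissues with edgeR, and with limma on log2(TPM + 0.5) it ran from 40.3% in skin to 61.7% in white adipose tissue. The species difference varied between tissues in 13747 of 14441 genes (edgeR interaction test), and 5699 genes were called in both directions in different tissues. The animals cannot be separated from the transcript models of each species, and TPM depends on which transcripts each table lists.

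Of 11253 genes tested in all tissues, 1449 were called the same way in all 8, of which 824 were higher and 625 lower in mole rats. The tissues come from the same animals, so the 8 calls of a gene are not independent. Without mole rats 3 to 5 the count was 1060 and without mole rats 1 and 2 it was 1453. The 8 named genes higher in mole rats were Pudp, Ddx46, Rnf151, Zcchc8, Mroh9, Nup58, Calcoco2 and Ldoc1. Calcoco2, an autophagy receptor, had 117 to 475 TPM over the mole rat libraries and 0 to 1.65 TPM over the mouse libraries. Pudp, a nucleotide phosphatase, had 9.10 to 52.4 TPM in mole rats and 0 to 0.112 TPM in mice, Ddx46, a splicing helicase, 13.8 to 68.9 and 0 to 0.524 TPM, and Nup58, of the nuclear pore, 11 to 56.1 and 0 to 0.18 TPM. Rnf151 had 35.2 to 127 and 0 to 0.389 TPM, Zcchc8 13.5 to 63.8 and 0 to 1.12 TPM, Ldoc1 39.1 to 233 and 0 to 1.31 TPM, and Mroh9 0.57 to 38 and 0 to 0.213 TPM. Pudp, Ddx46 and Zcchc8 had under 3 reads in 40, 36 and 38 mouse libraries. Whether mouse reads of these 8 genes were assigned to other or unnamed transcripts was not tested, so a difference in expression cannot be read from them. The 8 named genes lower in mole rats were Tlcd2, Pxmp2, Rps14, Myl9, Fth1, Mrps10, Crlf2 and Tmem106c. Rps14, a protein of the small ribosomal subunit, had 9.28 to 56.1 TPM in mole rats and 1120 to 7750 TPM in mice, and Fth1, the ferritin heavy chain, 0.668 to 172 and 1240 to 11300 TPM. Pxmp2, a peroxisomal channel, had 0 to 0.222 and 5.52 to 396 TPM, Tlcd2 0 to 0.175 and 5.66 to 267 TPM, and Myl9, a myosin light chain of smooth muscle, 0 to 4.67 and 3.65 to 784 TPM. Mrps10 had 0 to 2.75 and 26.6 to 59.0 TPM, Crlf2 0 to 3.32 and 4.44 to 45.4 TPM, and Tmem106c 0 to 3.61 and 6.26 to 61.6 TPM. Pxmp2 and Tlcd2 had under 3 reads in 39 and 38 mole rat libraries. Whether mole rat reads of the genes lower in mole rats were assigned to other transcripts, such as those named LOC, was not tested. Rps14, Rps18 and Fth1 have near-identical copies in mammals, and reads of copies named LOC in the mole rat were not joined to them.

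Among genes at 5 TPM or more in both species, Rps14, Rps18, Fth1 and S100g were among the 3 largest differences in a direction in more than 1 tissue. In liver Ptgr1 (456 ± 430 against 5.41 ± 1.84 TPM, n = 5 each; log2 fold change 6.32, or 5.62 without mole rat 2), Tspan13 and Aox1, an aldehyde oxidase, were higher in mole rats, and Rtn4 was lower (6.01 against 316 TPM). In kidney Kng1, the kininogen gene, was higher (1324 ± 282 against 7.46 ± 4.67 TPM, n = 5 each), as were Apoa2 (6.81, or 9.41 without mouse 5) and Acsm3, and S100g, a calcium-binding protein, was lower (13.1 against 5003 TPM). In lung Agr2 and Pigr, the receptor that carries antibodies across epithelia, were higher (log2 fold changes 6.15 and 5.82), and S100g was lower (-6.26). In muscle Sln, sarcolipin, a regulator of the calcium pump, was higher (6370 ± 793 against 14.9 ± 5.61 TPM, n = 5 each), as was Snurf (5.72), and Actc1, cardiac actin, was lower (-6.15). In skin S100a9, an antimicrobial protein of neutrophils and keratinocytes, was higher (6493 ± 5544 against 51.0 ± 12.5 TPM, n = 5 each; log2 fold change 7.12, or 6.51 without mole rat 1), as was Slurp1, and Ly6d was lower (47.8 against 2022 TPM). In spleen Timp1 (583 ± 1187 against 10.6 ± 3.31 TPM, n = 5 each) and Msr1 were higher, and Rsad2, the antiviral protein viperin, was lower (7.98 ± 13.2 against 416 ± 186 TPM, n = 5 each). Without mole rat 2 the log2 fold change of Timp1 there was 2.14 in place of 6.11, and that of Rsad2 was -7.85 in place of -5.47. In intestine Camk2n1 and Mdh1 were higher, and Spink4 was lower (-5.70, or -4.37 without mouse 1), while Pgc, a gastric protease, was higher (1066 ± 2133 against 5.33 ± 11.5 TPM, n = 5 each) with 4880 TPM in mole rat 2 alone. The call of Pgc was lost without mole rat 2 (log2 fold change 4.54, adjusted p = 0.1) and without mouse 2, 4 or 5 (adjusted p = 0.066, 0.067 and 0.07), and the log2 fold change was 12.61 without mouse 3 in place of 7.74. In white adipose tissue Retn, the adipokine resistin, was lower (9.43 ± 3.6 against 4875 ± 823 TPM, n = 5 each), as was Chpt1 (-6.49). The organ's own markers, Retn among them, averaged 9.01 to 10.41 there in mole rats and 11.05 to 11.74 in mice, as log2(TPM + 0.5). The muscle genes Tcap, Mb and Ckm were higher there, with Ckm at 6330 TPM in mole rat 5 and 456 TPM in mole rat 3 and 1.62 to 24.6 TPM in the other 3. Without mole rat 5 these calls were lost (log2 fold changes 3.72, 2.37 and 2.85, adjusted p = 0.053, 0.13 and 0.15), and the call of Ckm was also lost without mouse 1, 2, 3 or 4 (adjusted p = 0.06 to 0.067). Without mouse 5 the log2 fold changes of Tcap, Mb and Ckm were 8.62, 8.05 and 7.47, in place of 7.39, 6.92 and 6.50.

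Markers of other cell types differed between libraries of 1 tissue. In white adipose tissue 11 of 12 epithelial markers were higher in mole rats and 0 lower (camera adjusted p = 0.037; 0.99 with an estimated correlation), with mean log2(TPM + 0.5) of 5.84 and 6.63 in mole rats 1 and 4 and 1.71 to 2.97 in the other 3. There 17 of 29 extracellular matrix genes were lower and 0 higher (camera adjusted p = 0.0022; 0.99 with an estimated correlation), and 29 of 49 cell cycle genes were lower and 3 higher (camera adjusted p = 0.0031; 0.99 with an estimated correlation). In spleen 20 of 49 cell cycle genes were lower and 1 higher (camera adjusted p = 0.009; 0.99 with an estimated correlation). Ctrl, a pancreatic protease, had 10500, 2490, 0.322, 117 and 773 TPM in the spleens of mice 1 to 5 and 5.18 to 9.97 TPM in those of mole rats (log2 fold change -8.51, or -6.80 without mouse 1), and spleen markers averaged 5.57 in mole rat 2 and 6.94 to 7.73 in the other 4. Endothelial markers were lower in mole rats in liver (12 of 14) and lung (10 of 14), with a camera adjusted p of 0.037 each (0.99 with an estimated correlation). In kidney 28 of 43 DNA repair genes were higher and 11 lower (camera adjusted p = 0.046; 0.99 with an estimated correlation). In intestine the organ's own markers averaged 5.16 in mouse 1 and 9.45 to 9.92 in the other mice. Of the 272 tests of a list in a tissue camera called 17, of which 2 were higher and 15 lower, and 0 with an estimated correlation, while fry, which tests a list by itself, called 115. Without the length offset the calls of endothelial markers in liver and lung and of interferon-stimulated genes in lung were lost. The call of DNA repair genes in kidney was lost with the replicate block and without the animals numbered 3 or 5, and that of endothelial markers in lung without the same numbers. Endothelial markers in liver were not called without number 3, epithelial markers in white adipose tissue without number 1, and cell cycle genes in spleen without number 4. Interferon-stimulated genes in lung were not called without number 2, nor were nucleic acid sensing genes in white adipose tissue, and in skin the latter were not called without number 4. For camera other splits of the animals gave as many or more, so the counts of members are the measured result.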

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

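The tests of scaling, of the sign of the length trend, of the ratios of mean RPM, of the genes with a mean under 1 TPM in mice, of the depth of the mouse libraries, of sequence copies, and the splits of the fibroblast libraries were chosen after the result was seen. All 12 measured macrophage markers fell in old fibroblasts, with a median log2 fold change of -4.78, against a largest shift of 0.11 between scalings, which argues against scaling as the whole cause. Of 36 genes in a second leukocyte list with none of those markers, 34 were tested, 27 of them (79.4%) had a log2 fold change under -2, and 0 were called higher in old. The bound set beforehand for cells of another type in the young cultures was 80%. On the log2(RPM + 0.5) scale CX3CR1 and CLEC7A, at 1.49 and 1.22 RPM in young, could not reach -2 even with no reads in old. They had -1.957 and -1.751, so the 79.4% cannot decide, and this explanation stays open. By mean RPM 30 of the 34 (88.2%) were over 4-fold lower. CX3CR1 went from 1.49 to 0.0103 RPM, LCP1 from 37.8 to 0.579 RPM and LAPTM5 from 27.9 to 0.0211 RPM, while ARHGDIB went from 22.3 to 13.3 RPM. Leukocytes in the young cultures are a candidate explanation. A difference between the old and young fibroblasts themselves stays open and untested, since these are the groups compared. The labels do not state what old and young mean.

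Among the 824 genes higher in all 8 mole rat tissues, 3 had under 3 reads in each mouse library, and 54 had a mean under 1 TPM in mice in every tissue. If mouse transcripts were missing from the match to gene names, the mouse tables would lack the canonical transcript of these genes. They held it for 3 of the 3 genes and 783 of 821 others (-4.6 percentage points lower, Fisher exact p = 1), which is too few genes to decide. They held it for 53 of the 54 genes (98.1%, exact interval 90.1 to 100) and 733 of 770 others (95.2%, -3 percentage points lower, Fisher exact p = 0.51), which argues against a missing canonical transcript for the 54. It cannot show whether reads were assigned to other or unnamed transcripts, and this was not tested. Unnamed transcripts took 2.51 to 23.25% of the reads of a mouse library. Median reads in shared genes were 1.07 times as many in mice as in mole rats, which argues against low depth, while wrong gene symbols and a difference between the species were not tested.

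The deviations of mole rats 1 and 2 from the tissue means correlated across genes in 7 of 8 tissues (r from -0.23 to 0.58, median 0.32, against -0.2 and 1 tissue for mice 1 and 2), and the largest differences from mole rats 3, 4 and 5 were in a few genes, with Gapdh at 216 to 7940 TPM against 2.79 to 135 TPM over the 8 tissues and Fth1 at 0.668 to 11.4 TPM against 6.72 to 172 TPM. Each of the 6 pairs across these animals had 5 or 6 genes over 4-fold apart the same way in all 8 tissues, and the other 4 mole rat pairs and the 10 mouse pairs had 0. Read depth overlapped in 6 of the 8 tissues, which argues against a difference in read depth as the cause. The deviation of mole rat 1 fell with gene length in 5 tissues and rose in 3, each by over 3 standard errors, which argues against gene length for genes apart the same way in all 8, while a weak length bias in other genes stays open (median absolute Spearman rho 0.1, at the bound set beforehand). For those 5 or 6 genes a variant against the reference or reads shared between copies also stays open, with no sequence searched, and for the wider correlation no biological explanation was tested since the labels give none.

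Other splits of the same samples were counted. In fibroblasts the real split gave 8542 genes and 12 lists, and the highest of the other splits gave 0 genes and 10 lists. With 10 splits, of which 1 gave as many genes and 1 as many lists, there are too few for a share under 0.05. For the animals 40 splits were drawn per tissue, and only the real one gave as many genes. Every other split mixed the species, so the species difference widened the spread within its groups and lowered its calls. These splits therefore do not decide about chance for these counts. They also cannot separate the species from a technical difference that follows it. The highest of the other splits called 0 genes in liver, kidney, lung, muscle and skin, 1 in intestine, 1 in white adipose tissue and 91 in spleen. For the 1449 genes called the same way in all 8 tissues the highest other was 0. For the species by tissue interaction 1 of 21 splits gave as many, with 3816 of 4000 genes in the real split and 2028 in the highest other. For the pairs of list and tissue all 40 splits gave as many as the 17 called by camera, with up to 86, so chance cannot be excluded there. The other 9 splits of the fibroblasts, with 0 genes each, gave 7 to 10 lists, so the camera calls there do not set the real split apart.

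In 23 of 144 groups of 5 libraries 1 animal lay far from the other 4, for 22 groups of a key gene and 1 of organ markers. The measure was Dixon's ratio, which by chance puts about 1 in 20 independent groups of normally distributed values there, or 7.2. The groups share animals and the key genes were taken as TPM without a log, so the chance rate here is not known. Dnmt1 was 5.08 TPM in muscle of mole rat 3 (others 5.69 to 5.90), 28.5 TPM in intestine of mouse 5 (16.8 to 20.1) and 21.2 TPM in white adipose tissue of mole rat 5 (26.3 to 27.9). Uhrf1 was 4.72 TPM in liver of mouse 4 (0.904 to 1.65), 27.1 TPM in lung of mouse 4 (4.86 to 10.9), 6.32 TPM in muscle of mouse 5 (0.593 to 2.20), 71.7 TPM in skin of mouse 4 (13.2 to 22) and 25.2 TPM in skin of mole rat 1 (4.53 to 10.1). Cgas was 0.519 TPM in liver (0.232 to 0.292) and 0.892 TPM in kidney (0.182 to 0.361) of mole rat 1. Isg15 was 54.7 TPM in kidney (12.4 to 22.7) and 83.5 TPM in white adipose tissue (21.4 to 33.3) of mole rat 1, and 972 TPM in spleen of mole rat 2 (61.9 to 144). Cdkn1a was 103 TPM in spleen of mole rat 2 (5.63 to 16.6) and 11.7 TPM in liver of mouse 4 (2.25 to 3.82). Has2 was 1.55 TPM in muscle (0.650 to 0.788) and 1.72 TPM in intestine (0.488 to 0.807) of mouse 1, and 34.9 TPM in skin of mouse 5 (3.23 to 11). Hpse was 0.468 TPM in muscle of mole rat 3 (0.940 to 1.12), 29.5 TPM in intestine of mouse 1 (15.4 to 18.5), 50.6 TPM in white adipose tissue of mole rat 1 (5.57 to 15.3) and 84.4 TPM in white adipose tissue of mouse 2 (21.8 to 29.2). Intestine markers averaged 5.16 on the log2(TPM + 0.5) scale in intestine of mouse 1 (9.45 to 9.92).

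The species difference varied between tissues for 7 of the 8 key genes tested. The adjusted p of the edgeR interaction was 0.00057 for Dnmt1, 3.4e-08 for Uhrf1, 1.3e-05 for Cgas, 6.5e-08 for Irf7, 4.9e-05 for Isg15, 0.0064 for Cdkn1a and 5.3e-08 for Hpse.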

How the results depend on the processing

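The fits on recovered reads, on TMM-scaled RPM and on some of the mole rats were chosen after the result was seen. Leaving out 1 library at a time gave 7657 to 9153 fibroblast genes (4508 to 5361 higher, 3126 to 3792 lower) and 12 lists each time. In the tissues it gave 8303 to 8537 genes in liver, 9705 to 10128 in kidney, 9603 to 9936 in lung, 6706 to 8000 in spleen, 8706 to 9134 in muscle, 6965 to 7502 in skin, 6572 to 7921 in intestine, 7335 to 7934 in white adipose tissue and, without 1 animal in every tissue, 1306 to 1437 the same way in all 8 (757 to 822 higher, 549 to 632 lower). Without 1 animal number in both species 15 to 19 pairs of list and tissue were called. In spleen Ereg ranged from -2.53 to 0.66 (0.36 with all animals), Tap1 from -0.68 to 0.30 (0.08) and Isg15 from -1.74 to 0.72 (0.29), each lowest without mole rat 2. Over 12 alternatives 8382 to 9310 fibroblast genes were called, and the named fibroblast genes kept their direction and their call. With an estimated correlation 5 fibroblast lists and 0 pairs of list and tissue were called. Of the MeDIP windows 332 passed an adjusted p under 0.01 and 478 under 0.05.

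With an absolute log2 fold change over 1 the calls were 5271 in liver, 5428 in kidney, 5309 in lung, 5020 in muscle, 4910 in spleen, 4224 in skin, 4642 in intestine, 4908 in white adipose tissue and 563 in all 8 (357 higher, 206 lower), as fewer genes reach that change. Among the named genes run under the alternatives, the sign of the log2 fold change, called or not, turned without the length offset for Adar in kidney (0.05) and muscle (0.13), Hyal1 in lung (-0.05), B2m in spleen (0.56) and intestine (1.13), Cgas in spleen (-1.06) Cdkn1a in skin (-0.68) and Gins2 in white adipose tissue (-0.16). So did Ifngr2 in kidney (-1.24), lung (-0.55), spleen (-0.40), skin (-0.35) and white adipose tissue (-0.83), and Mbd3 in kidney (0.59), lung (0.50), spleen (0.72), skin (0.62), intestine (0.56) and white adipose tissue (0.31). With mole rats 1 and 2 alone Ddb2 in kidney (0.49) and Ckm in white adipose tissue (-0.80) turned, and with mole rats 3, 4 and 5 alone Ereg (-2.89), Tap1 (-0.81), Irf7 (-1.51), Isg15 (-2.03) and Cdkn1a (-0.99) in spleen. The cause was not tested. Calls of named genes in a tissue were lost 27 times without the length offset, 115 with an absolute log2 fold change over 1, 19 with the replicate block, 17 with limma on log2(TPM + 0.5), 18 on log2(TPM + 1), 7 with DESeq2, 4 with no filter, 1 with RLE and 1 with the stricter filter. With mole rats 1 and 2 alone 65 were lost, and with mole rats 3, 4 and 5 alone 20, both with fewer animals. Those lost without the length offset included Adar in liver and white adipose tissue, Icam1 in spleen and white adipose tissue, Fadd in spleen and muscle, Mdm2 in spleen, B2m in muscle, Helz2 in skin, Sirt7 and Cdkn1a in intestine. With the replicate block they included Cgas in liver, lung, muscle and skin, Has2 in kidney, Sirt6 in spleen, Adar in muscle, Pgc in intestine and Ckm in white adipose tissue. DESeq2 lost Has2 in kidney, Timp1 in spleen, and Tcap, Mb and Ckm in white adipose tissue. With the replicate block 8937 fibroblast genes (5280 higher, 3657 lower), 12 lists, and 1313 genes in all 8 tissues (743 higher, 570 lower) were called, against 8542, 12 and 1449. In tissues the numbers do not pair the samples: correlations of deviations for the same number were -0.42 to 0.33. In fibroblasts they were 0.27, -0.04 and 0.26 for the same number and -0.297 to 0.149 for different numbers. A pairing of the fibroblast libraries by number therefore stays open. Alternatives for transposon families and for methylation with expression were not run.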

Other observations

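No test in this part was chosen after the result was seen, but the genes mentioned were picked after their values were seen, from those named by rule. Several other named genes of the fixed lists differed the same way in all 8 tissues. In mole rats Sod2, the mitochondrial superoxide dismutase, was higher, with log2 fold changes from 0.86 to 4.23, as were Keap1 (0.36 to 1.25), which holds back the antioxidant factor NRF2, and Lss (0.99 to 4.77), an enzyme of sterol synthesis. Ercc1 (0.96 to 2.54), of nucleotide excision repair, and Gins2 (1.58 to 4.10), of the replication machinery, were higher, while Ercc2 (-1.24 to -0.57), Ddb1 (-1.16 to -0.42) and the checkpoint kinase Chek2 (-4.20 to -0.98) were lower. Higd1a (0.67 to 1.53) was higher and Pdk1 (-3.72 to -0.84) lower, both of the hypoxia list. Mki67 (-5.84 to -1.59) and Cenpa (-4.40 to -1.40), genes of dividing cells, were lower. The ribosomal protein genes Rpl37 (1.67 to 2.33) and Rps16 (1.39 to 1.94) were higher and Rpl38 (-2.14 to -1.23) lower. In spleen the log2 fold change of Sod2 was 1.63 without mole rat 2 in place of 4.23, and the call of Chek2 was lost without any of 6 of the 10 animals. The call of Keap1 was lost without any of 4 of the 10 in muscle and in white adipose tissue. Without the length offset Gins2 was not called in spleen, muscle, skin or white adipose tissue, nor Lss in skin, intestine or white adipose tissue, nor Ercc2 in spleen. Camera called the antioxidant, cholesterol, hypoxia and ribosomal lists in no tissue (smallest adjusted p = 0.46, 0.32, 0.2 and 0.41).

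Some cell type markers also differed. Adgre1, a macrophage marker of mice, was lower in mole rats in all 8 tissues (-6.37 to -2.84), and Cd163, a scavenger receptor of macrophages, was lower in the 7 tissues where it was tested (-6.13 to -3.41). Of the same list Cd14 was higher in 5 tissues and lower in 1 (-1.68 to 2.98, the lower call in intestine lost without any of 7 of the 10 animals), Csf1r was lower in 6, and camera called the list in no tissue (smallest adjusted p = 0.32). Tyr, the tyrosinase of pigment cells, was lower in all 8 (-8.57 to -2.41), and so was Sparc, a matrix protein (-2.42 to -0.72). The call of Sparc in intestine was lost without any of 3 of the 10 animals, and that of Tyr in skin without mouse 2. Without the replicate that moved it most, Tyr was -10.12 in place of -8.04 in kidney (mole rat 1), -9.03 in place of -5.95 in muscle (mole rat 1) and -10.21 in place of -6.87 in white adipose tissue (mole rat 5), and Cd163 in liver was -7.74 in place of -6.13 (mole rat 4). Gsdme, a gasdermin, was lower in 7 tissues (in spleen the call was lost without mole rat 1 or mouse 3) and higher in 1, from -4.68 in liver to 5.14 in intestine.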
